A study of Homo sapiens with 6 samples.

How the data were processed

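RNA was measured in COLO 205 cells, a line established from a human colon adenocarcinoma, in 6 libraries: 3 from control cultures and 3 from cultures given 500 nM SB204741, an antagonist of the serotonin receptor HTR2B, for 3 days. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with Illumina's stranded mRNA kit. Neither the vehicle of the control cultures nor their time in culture is given in the sources used here. It is also not given whether the 3 libraries of a group came from separate cultures. P-values therefore measure only the spread between these samples, which may be technical.

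The deposited files are transcript tables from kallisto on genome build GRCh38, per the submitters' processing notes, which give no version. Each table holds 187626 transcripts, and per the file headers each transcript has an estimated count and a TPM value. The deposited estimated counts were not normalized, and the deposited TPM values are scaled for transcript length and depth by the authors' run of kallisto. Of the 187626 transcripts, 169943 matched the GENCODE release 29 annotation by their versioned identifier. A further 15328, from alternate loci, were joined to their gene through that release's symbol table, 201 were kept as a gene of their own, and 2154 had no gene name. The 2154 held between 0.224% and 0.238% of a library's counts and stayed out of library sizes and tests. The transcript set holds no long noncoding RNAs of the list written for them.

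Expected counts were summed over each gene's transcripts, giving 35610 genes, of which 19951 are protein coding, and rounded to whole numbers. Library totals ran from 24569405 to 32131277 expected counts. In a library of this size a count of 0 allows up to 3 counts, or 0.093 to 0.122 CPM, and this limit covers counting error only. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), scaled by TMM and tested with edgeR 4.0.16 by the quasi-likelihood test (legacy=FALSE, not robust, two-sided) in R 4.3.3, with no covariates. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Means ± SD are of TPM over the 3 libraries of a group. Fold changes come from the count model and need not equal the ratio of the TPM means.

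Before the data were examined, 39 gene lists were written for metabolism, stress responses, growth, colon differentiation, the serotonin system and markers of other cell types, with 962 entries, of which 945 matched a gene of the transcript set. Of these lists, 37 had at least 5 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 37 lists. Each was also tested with the correlation estimated from the residuals and with fry. The estimated setting of camera also lowers the degrees of freedom, from 15596 to 4. An added test therefore kept 15596 and used each list's estimated correlation, with estimates below 0 set to 0. The lists share members, for example NQO1 between the aryl hydrocarbon receptor and NRF2 lists and SLC2A1 between the glycolysis and hypoxia lists.

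The rule for named genes was also set before the data were examined. It takes HTR2B and every gene of the serotonin list with a mean of at least 1 TPM. It takes up to 7 protein-coding genes per direction with the largest fold change, among those past the threshold with a mean of at least 5 TPM and groups that do not overlap in log2 CPM. From each of the 6 lists with the smallest camera p it takes up to 3 members past the threshold, or the 2 with the smallest p where none passed, and from any other list with at least 3 members past the threshold it takes 1. Pseudogenes are not named.

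The share of each named gene's 31-base words found in no other gene of the transcript set was computed, since kallisto divides reads between transcripts that share sequence. A word and its reverse complement were taken as the same word, so overlap with a gene on the opposite strand counts as shared. Such overlap would divide reads only in a kallisto run that ignored the strand, which was not examined. The test was checked on simulated counts for the 2 groups, with 15436 genes past the filter. Changed genes were drawn from those with a mean of at least 50 counts, so the shares called do not cover genes with fewer. Of 50 genes changed per size, the test called 52% at 1.2-fold, 92% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 15 false calls among 186. In simulated data with no change camera called 0 of 37 lists. It called the mitosis list and 0 others when that list was raised by 0.15 on the log2 scale. Genes were simulated as independent of each other, whereas the estimated correlation of the mitosis list was 0.42 in the data. The simulation therefore gives no rate of false calls for lists whose members vary together.

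The alternatives were median-ratio size factors, total counts only, other filters on low counts, DESeq2 1.42.0, limma-voom, the legacy and the robust form of the quasi-likelihood test, limma on log2(TPM + 1) and log2(TPM + 0.1), an offset for transcript length, protein-coding genes only, the replicate number as a block and leaving out each library in turn. Transcripts of the primary assembly only, a filter at a mean TPM of 1, a correction of each library for GC content, that added test of the lists and the robust form for named genes were added after seeing the data. Python 3.11.15 with pandas 2.3.3 summed the tables, and matplotlib 3.10.9 drew the figures.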

Results

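The transcriptome of COLO 205 colon adenocarcinoma cells was compared between 3 control libraries and 3 libraries from cells given 500 nM SB204741 for 3 days, in a study of tumour metabolism and the serotonin receptor HTR2B. The control libraries held 27387272, 30062323 and 31947251 expected counts and the SB204741 libraries 24569405, 32131277 and 27652496. Protein-coding genes took 98.6% to 98.7% of the counts, and between 14043 and 14325 genes reached 1 TPM. Pearson correlations of log2 CPM across genes ran from 0.990 to 0.995 over all pairs of libraries, with a mean of 0.9936 within groups and 0.9928 between them. The first principal component held 32.4% of the variance. On it control replicates 1, 2 and 3 lay at -30.4, 2.7 and -2.3, and SB204741 replicates 1, 2 and 3 at 14.2, 7.9 and 7.9. The groups did not overlap on it, and control replicate 1 lay apart from the other 5 libraries. All pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 2.6 to 12.4).

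Transcripts of HTR2B, the receptor that SB204741 blocks, were barely detected in either group. The gene (chromosome 2, 231108230 to 231125118, GRCh38) had 2.3 expected counts over the 3 control libraries and 2 over the 3 SB204741 libraries, 4.3 in all 6, and no library exceeded 0.042 TPM. Both groups lay under the floor of 3 counts, so no fold change is given, and a difference was not detectable at this depth. HTR2B shared 24.1% of its 31-base words with PSMD1. Of 17 serotonin receptor genes, 16 had a mean under 1 TPM. The exception was HTR1D, a Gi-coupled receptor, at 4.29 ± 0.72 TPM in control and 3.45 ± 0.09 TPM in SB204741 cells (SD, n = 3; adjusted p = 0.349).

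Other genes of the serotonin system were expressed and none passed the test. DDC, which makes serotonin from 5-hydroxytryptophan, stood at 30.1 ± 3.2 TPM in control and 26.7 ± 1.08 TPM in SB204741 cells (SD, n = 3), with a log2 fold change of -0.15 ± 0.07 (SE; adjusted p = 0.417). MAOA, which breaks serotonin down, stood at 27.3 ± 1.53 and 27 ± 0.88 TPM (SD, n = 3), with a log2 fold change of 0.00 ± 0.05 (SE; adjusted p = 0.991). Mean TPM over the 6 libraries was 3.83 for AANAT, 3.41 for the transporter SLC6A4, 2.31 for the hydroxylase TPH2, 1.55 for MAOB and 1.06 for the vesicle transporter SLC18A2, with adjusted p between 0.477 and 0.934. SLC18A2 shared 51.3% of its 31-base words, matched on either strand, with PDZD8, so its level may be uncertain. For the serotonin list, 0 of 10 tested members passed, 0 passed adjusted over the list alone (1 lower without control replicate 2), and the camera adjusted p was 0.77.

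Treatment with SB204741 was followed by a large rise of CYP1A1 and by changes of less than 2-fold in the other called genes, apart from 3 genes near 0 counts in 1 group that are given at the end. CYP1A1 (chromosome 15, 74719542 to 74725610, minus strand), a cytochrome P450 enzyme of xenobiotic metabolism, rose 9.31-fold, from 14.1 ± 9.85 to 126 ± 7.91 TPM (SD, n = 3). FABP1 (chromosome 2, 88122982 to 88128116, minus strand), the liver-type fatty acid binding protein, rose 1.84-fold, from 44.5 ± 5.72 to 80 ± 7.51 TPM. The EGF receptor ligands AREG and EREG rose 1.53-fold and 1.52-fold, the adhesion molecule CEACAM5 rose 1.47-fold, the uridine phosphorylase UPP1 rose 1.4-fold and the stress-induced transcription factor DDIT3 rose 1.39-fold. The semaphorin receptor PLXND1 fell 1.6-fold, C20orf204 fell 1.52-fold and the calpain family member CAPN6 fell 1.42-fold.

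Of 15598 tested genes, 31 were higher and 5 lower with SB204741 by edgeR's quasi-likelihood test at the adjusted threshold of 0.05. The log2 fold changes were 3.22 ± 0.29 for CYP1A1 (adjusted p = 0.000875), 0.88 ± 0.10 for FABP1 (0.00443), 0.56 ± 0.07 for CEACAM5 (0.00443), 0.48 ± 0.06 for DDIT3 (0.0048), 0.48 ± 0.08 for UPP1 (0.0274), 0.61 ± 0.10 for AREG (0.0279) and 0.60 ± 0.11 for EREG (0.0387), each with its SE. They were -0.67 ± 0.12 for PLXND1 (0.0451), -0.61 ± 0.10 for C20orf204 (0.0274) and -0.51 ± 0.09 for CAPN6 (0.032). In log2 CPM the groups did not overlap for any of the 36 genes, against 18.6% of tested genes and 10% by chance; in TPM they did not overlap for 35, AHRR being the exception, against 17.4% of tested genes. Of the 36 genes, 26 changed by less than 1.5-fold. An unadjusted p under 0.05 was reached by 1988 genes, where 780 would be reached by chance. CYP1A1 varied among controls, with 6.94, 25.4 and 10.1 TPM in replicates 1 to 3, against 122, 122 and 135 TPM with SB204741; its fold was 14.98 without control replicate 2 and 7.52 without control replicate 1.

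The counts differed between tests and with single libraries left out: DESeq2 called 144 higher and 47 lower, an offset for transcript length left 7 and 0, and limma on log2(TPM + 1) called 0, with 1640 genes at an unadjusted p under 0.05. Of the 36 genes, 36 remained without control replicate 1 or control replicate 2, and 9 without control replicate 3. Without SB204741 replicate 1, 2 or 3 in turn, 9, 13 and 8 remained. In all 6 of these fits 6 genes passed: CYP1A1, FABP1, CEACAM5, AHRR, AC008758.1 and a processed pseudogene. For AC008758.1 and the pseudogene, only 0.3% and 32.7% of the 31-base words occurred in no other gene. Among named genes, the robust form of the test ended the calls of CYP1A1 (adjusted p = 0.14), AREG (0.21), EREG (0.26) and PLXND1 (0.16).

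**Figure D1:**
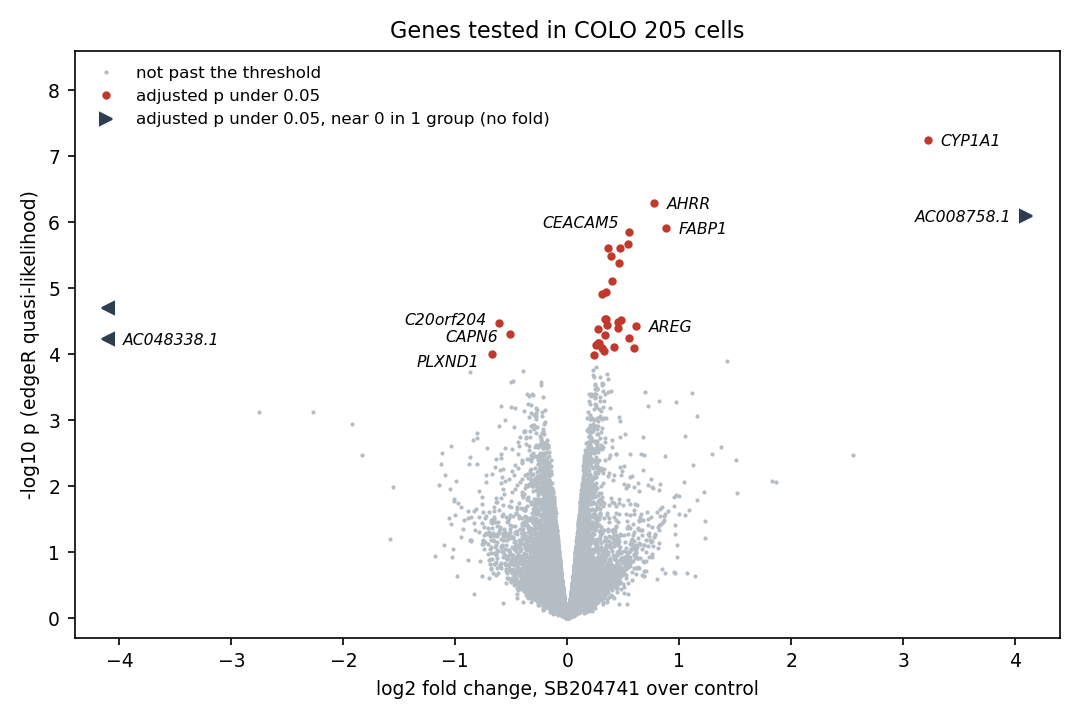
Each point is 1 of 15598 tested genes, with the log2 fold change (SB204741 over control) on the x axis and -log10 of the unadjusted p of edgeR's quasi-likelihood test on the y axis; red points are past the adjusted threshold of 0.05. CYP1A1 lies at 3.22 and the other red points within 0.88 of 0; 3 called genes near 0 counts in 1 group are drawn as triangles at the edge because their fold is not given.

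Target genes of the aryl hydrocarbon receptor, a ligand-activated transcription factor that senses xenobiotics, were higher as a group. Of the 10 tested members, 5 rose, 0 fell and 5 did not pass, and 8 were higher adjusted over the list alone. The 5 calls became 3 (CYP1A1, AHRR and UGT1A6) without control replicate 3, SB204741 replicate 1 or SB204741 replicate 2, and 2 (CYP1A1 and AHRR) without SB204741 replicate 3, and TIPARP was called as well without control replicate 1. AHRR, which encodes a repressor of the receptor, rose 1.71-fold (log2 fold change 0.78 ± 0.08, SE; adjusted p = 0.00392), and UGT1A6, a glucuronosyltransferase, rose 1.28-fold, from 104 ± 5.26 to 136 ± 5.28 TPM (0.36 ± 0.04; adjusted p = 0.0048). Outside the rule for named genes, and chosen after their values were seen, the other called members were the aldehyde dehydrogenase ALDH3A1 (0.46 ± 0.07; adjusted p = 0.0274) and NFE2L2, which encodes the transcription factor NRF2 (0.26 ± 0.05; adjusted p = 0.0379). Among the members that did not pass, the log2 fold change was 0.87 ± 0.35 for CYP1B1, 0.27 ± 0.07 for TIPARP, 0.14 ± 0.05 for NQO1 and -0.08 ± 0.30 for LRAT. For CYP1A2, which did not pass either, it was 0.46 (edgeR adjusted p = 0.49). Mean counts of CYP1B1, CYP1A2 and LRAT were low, at 14, 26.8 and 24.7 in control and 24, 33.8 and 21.9 with SB204741. The list's median log2 fold change was 0.41 (camera adjusted p = 2.6e-13). It was the only 1 of 37 lists still called with an estimated correlation at 4 degrees of freedom (camera adjusted p = 0.049). At the 15596 degrees of freedom of the preset test, the NRF2 (8.6e-08), interferon (0.0012) and colonocyte (0.017) lists were called as well. The estimates of the aryl hydrocarbon receptor (-0.06) and NRF2 (-0.02) lists were set to 0 there. For these lists that test was laxer than the preset correlation of 0.01. UGT1A6 shared sequence with other genes of its locus, with 45.4% of its 31-base words in no other gene, against 99.2% for CYP1A1 and 96.8% for AHRR. For AHRR, the offset for transcript length gave a log2 fold change of 0.36 (adjusted p = 0.44), and its TPM of 3.99 ± 0.95 in control and 5.39 ± 0.88 with SB204741 overlapped between groups.

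**Figure D2:**
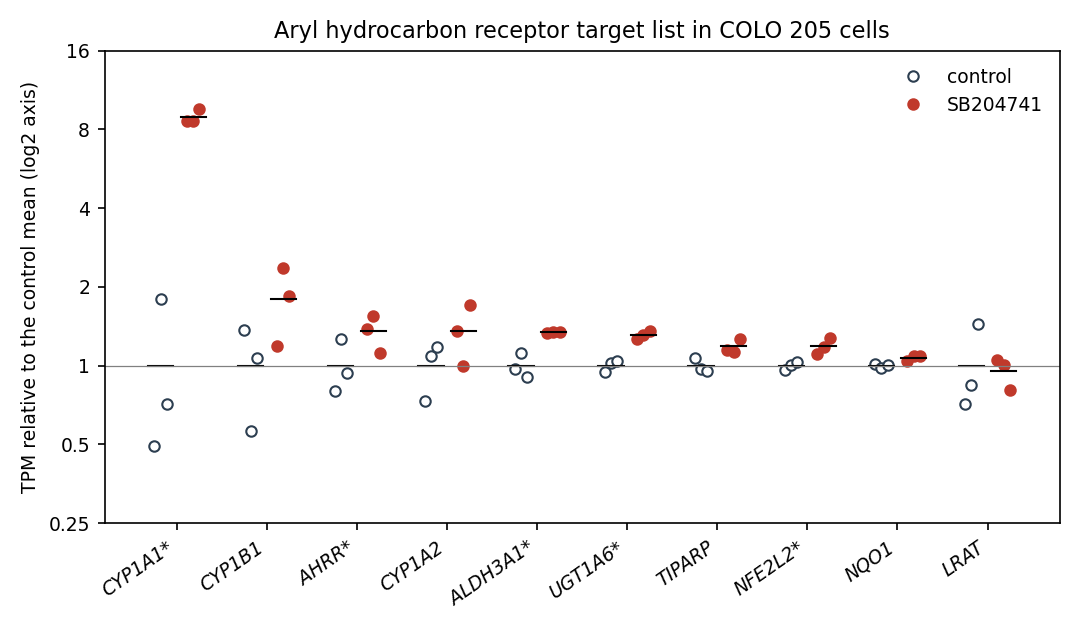
TPM of the 10 members of the aryl hydrocarbon receptor target list in each library, divided by the control mean of that gene, on a log2 axis; open circles are control and red circles SB204741 libraries, bars are group means and an asterisk marks genes past the adjusted threshold of 0.05. CYP1A1 stands at 122, 122 and 135 TPM with SB204741 against 6.94, 25.4 and 10.1 TPM in control.

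Genes of mitosis were slightly higher as a group by camera at the preset correlation, but not with an estimated one. Of 33 tested members, 3 rose and 30 did not pass, 17 were higher adjusted over the list alone, and 31 had a log2 fold change above 0, with a median of 0.14. The 3 calls became 0 without control replicate 3 or SB204741 replicate 1 and 1 (TTK) without SB204741 replicate 2 or 3, while 9 members were called without control replicate 1 and 7 without control replicate 2. The spindle checkpoint kinases TTK and BUB1 rose 1.38-fold and 1.21-fold (log2 fold change 0.46 ± 0.06, SE, adjusted p = 0.0064, and 0.28 ± 0.05, adjusted p = 0.0279), and the kinesin KIF2C rose 1.18-fold (0.24 ± 0.04; adjusted p = 0.0451). The camera adjusted p was 1.3e-16 (adjusted p = 0.43 with an estimated correlation). For DNA replication, 0 of 32 members passed and 0 adjusted over the list alone (camera adjusted p = 0.27), but the list passed as higher without control replicate 3 (0.012) or SB204741 replicate 3 (0.036). With an estimated correlation over all 6 libraries, its camera adjusted p was 0.88.

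Cells use the integrated stress response under amino acid shortage and protein folding stress. As a group its ATF4 targets were higher by camera at the preset correlation, but not with the estimated one of 0.50. Of 24 tested members, 4 rose and 20 did not pass, 9 were higher adjusted over the list alone, and the median log2 fold change was 0.24 (camera adjusted p = 2.1e-13; adjusted p = 0.44 with an estimated correlation). The 4 calls became 1 without control replicate 3 (CEBPB), SB204741 replicate 1 (DDIT3) or SB204741 replicate 3 (DDIT3) and 2 (DDIT3 and CEBPB) without SB204741 replicate 2, while 8 members were called without control replicate 2. The 9 adjusted over the list alone became 15 without control replicate 2 and 5 without control replicate 3, SB204741 replicate 1 or SB204741 replicate 3. DDIT3 rose from 364 ± 12.5 to 493 ± 35.6 TPM (SD, n = 3). The transcription factor CEBPB rose 1.27-fold (log2 fold change 0.35 ± 0.05, SE; adjusted p = 0.0145), and PPP1R15A, a regulatory subunit of the phosphatase that reverses the response, rose 1.28-fold (0.35 ± 0.06; adjusted p = 0.0278). Endoplasmic reticulum chaperones of the unfolded protein response had a median of 0.07, with 0 of 18 passing and 0 adjusted over the list alone (camera adjusted p = 0.00022; adjusted p = 0.49 with an estimated correlation). Without control replicate 2, 2 passed, HSPA5 and HERPUD1, and 6 adjusted over the list alone. Heat shock chaperones had a median of 0.08, with 0 of 15 passing and 4 higher adjusted over the list alone (camera adjusted p = 0.0016; adjusted p = 0.49 with an estimated correlation). The 4 became 0 without control replicate 3, SB204741 replicate 1 or SB204741 replicate 3, 2 without control replicate 1 or SB204741 replicate 2, and 6 without control replicate 2. In DDIT3, 71.1% of the 31-base words occurred in no other gene, and 21.5% were shared with MARS.

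Hypoxia response genes were higher as a group, with a median log2 fold change of 0.22: 0 of 20 members passed, 10 were higher adjusted over the list alone, and the camera adjusted p was 4.8e-11 (adjusted p = 0.48 with an estimated correlation). Without control replicate 1, 8 members were called and 16 were higher adjusted over the list alone. Without control replicate 2, 3 were called. Without control replicate 3 or SB204741 replicate 3, 0 were called and 5 were higher adjusted over the list alone. The histone demethylase KDM3A had a log2 fold change of 0.26 ± 0.05 (SE, adjusted p = 0.0642) and ANKRD37 of 0.46 ± 0.11 (adjusted p = 0.118). ANKRD37 shared 33.5% of its 31-base words with UFSP2. The lists of metabolic enzymes and transporters past the threshold had medians between -0.07 and 0.11. For glycolysis and lactate export, 0 of 21 members passed, 3 were higher adjusted over the list alone, and the median was 0.11 (camera adjusted p = 0.0003; adjusted p = 0.7 with an estimated correlation). These 3 were the glucose transporter SLC2A1 (0.33 ± 0.08), the hexokinase HK2 (0.29 ± 0.07) and PGK1 (0.21 ± 0.06), chosen after their values were seen. Their number became 0 without control replicate 3, SB204741 replicate 1 or SB204741 replicate 3 and 8 without control replicate 1, and 2 members were called without control replicate 1 or 2. Nuclear-encoded genes of oxidative phosphorylation had a median of 0.04, with 0 of 77 passing and 0 adjusted over the list alone (camera adjusted p = 0.0027; adjusted p = 0.88 with an estimated correlation). The 13 genes of the mitochondrial genome had a median of -0.07, with 0 passing and 0 adjusted over the list alone (camera adjusted p = 0.0098; adjusted p = 0.77 with an estimated correlation; 3 lower over the list alone without control replicate 2), and took 6.13 ± 0.27% of counts in control and 5.74 ± 0.19% in SB204741 libraries (SD, n = 3). Fatty acid synthesis had a median of -0.06, with 0 of 17 passing and 2 lower adjusted over the list alone (camera adjusted p = 0.039; adjusted p = 0.64 with an estimated correlation). The 2 became 0 without control replicate 3, SB204741 replicate 1 or SB204741 replicate 3, and 5 without control replicate 2, where FASN and MLXIPL were called over all genes. Leaving out control replicate 3 ended the calls of nuclear-encoded oxidative phosphorylation (adjusted p = 0.44), glycolysis (0.053) and fatty acid synthesis (0.095), and leaving out SB204741 replicate 1 those of the mitochondrial genes (0.13) and fatty acid synthesis (0.066). Leaving out SB204741 replicate 2 ended those of nuclear-encoded oxidative phosphorylation (0.056) and fatty acid synthesis (0.057), and control replicate 1 that of fatty acid synthesis (0.15).

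The remaining metabolic lists did not pass. The camera adjusted p was 0.37 for the tricarboxylic acid cycle, 0.63 for the pentose phosphate pathway, 0.77 for serine and one-carbon metabolism, 0.19 for glutamine and amino acid transport, 0.77 for nucleotide synthesis, 0.37 for cholesterol synthesis and uptake and 0.77 for fatty acid oxidation. None of the members of these lists passed the edgeR test over all genes, and adjusted over the list alone only glutamine and amino acid transport held any, with 1 higher and 1 lower. Leaving out 1 library changed this for some of them, with camera at the preset correlation. With an estimated correlation over all 6 libraries, the camera adjusted p was 0.88 for both the glutamine and the cholesterol list. Without control replicate 2 the glutamine list passed as higher (0.045) and the cholesterol list as lower (0.045). In that fit SLC3A2 was called higher and GLUL, LSS and OGDH lower. Over the list alone there were 3 higher and 1 lower for glutamine, 5 lower for cholesterol, 1 higher and 1 lower for serine and one-carbon metabolism, 2 lower for fatty acid oxidation and 1 lower each for the tricarboxylic acid cycle and nucleotide synthesis. Without control replicate 1, RRM2 and INSIG1 were called higher. Over the list alone there were then 1 higher and 2 lower for glutamine, 2 higher for cholesterol and 1 higher and 1 lower for nucleotide synthesis. The glutamine list also passed as higher without control replicate 3 (0.013), where its members over the list alone fell to 0, as they did without SB204741 replicate 1 or 3, and to 1 lower without SB204741 replicate 2.

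Wnt and beta-catenin targets mark stem and progenitor cells of the colon crypt. As a group they were lower by camera at the preset correlation, but not with an estimated one. None of 19 tested members passed on its own, 12 were lower and 1 higher adjusted over the list alone, and the median log2 fold change was -0.16 (camera adjusted p = 6.2e-08; adjusted p = 0.47 with an estimated correlation). The 12 became 0 without control replicate 3, 8 without SB204741 replicate 1, 7 without SB204741 replicate 2 and 5 without SB204741 replicate 3, while 8 members, EPHB2 and EPHB3 among them, passed without control replicate 2. The ephrin receptors EPHB2 and EPHB3 had log2 fold changes of -0.35 ± 0.08 (SE; adjusted p = 0.0881) and -0.32 ± 0.07 (adjusted p = 0.111). Genes of colonocyte differentiation were higher, with 3 of 12 tested members called and 4 adjusted over the list alone. The camera adjusted p was 2.1e-06 (adjusted p = 0.33 with an estimated correlation). The list had 23 written members, and the tested ones had a median log2 fold change of 0.10 against a mean of 0.26. FABP1 and CEACAM5, given above, were called along with CEACAM6 (0.46 ± 0.08; adjusted p = 0.0279), which was chosen after its value was seen and whose call ended without control replicate 3 or any 1 of the 3 SB204741 libraries. In CEACAM5, 76.5% of the 31-base words occurred in no other gene, and CEACAM6 shared 6.2% of its words with CEACAM5. With an estimated correlation over all 6 libraries, the camera adjusted p of the goblet and secretory list was 0.77. The goblet and secretory list (camera adjusted p = 0.13) and the enteroendocrine list (0.72) did not pass, but the goblet list passed as higher without control replicate 2 (0.045) or SB204741 replicate 1 (0.027) and, at the threshold, after GC correction. Of its members 0 of 11 were called, and 0 adjusted over the list alone (1 higher without control replicate 1 or 2).

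Targets of NRF2, the transcription factor of the oxidative stress response, had a median log2 fold change of 0.10. None of 20 tested members passed, 7 were higher adjusted over the list alone, and the camera adjusted p was 4.8e-07 (adjusted p = 0.078 with an estimated correlation). In the added test that kept the degrees of freedom of the preset test, with the list's correlation set to 0, the camera adjusted p was 8.6e-08. The 7 became 4 without control replicate 3, SB204741 replicate 2 or SB204741 replicate 3, and AKR1C1 and AKR1C2 were called over all genes without control replicate 2. The aldo-keto reductases AKR1B10 and AKR1C1 had log2 fold changes of 0.70 ± 0.15 (SE) and 0.34 ± 0.07, each with an adjusted p of 0.0881. AKR1C1 had 64.3% of its 31-base words in no other gene and shared 35.1% with AKR1C2. AKR1B10 had 69.3% in no other gene and shared 18.8% with AKR1B15. Its mean counts were low, at 80.1 in control and 120.5 with SB204741. Interferon-stimulated genes had a median of 0.14, with 0 of 27 passing and 2 higher adjusted over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.22 with an estimated correlation). The 2 became 0 without control replicate 2, SB204741 replicate 2 or SB204741 replicate 3, and 1 without control replicate 1 or SB204741 replicate 1. Fry, which tests whether a list's genes move one way on balance without setting them against other genes, called 2 lists, the aryl hydrocarbon receptor targets (adjusted p = 0.00088) and the NRF2 targets (0.0078).

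**Figure D3:**
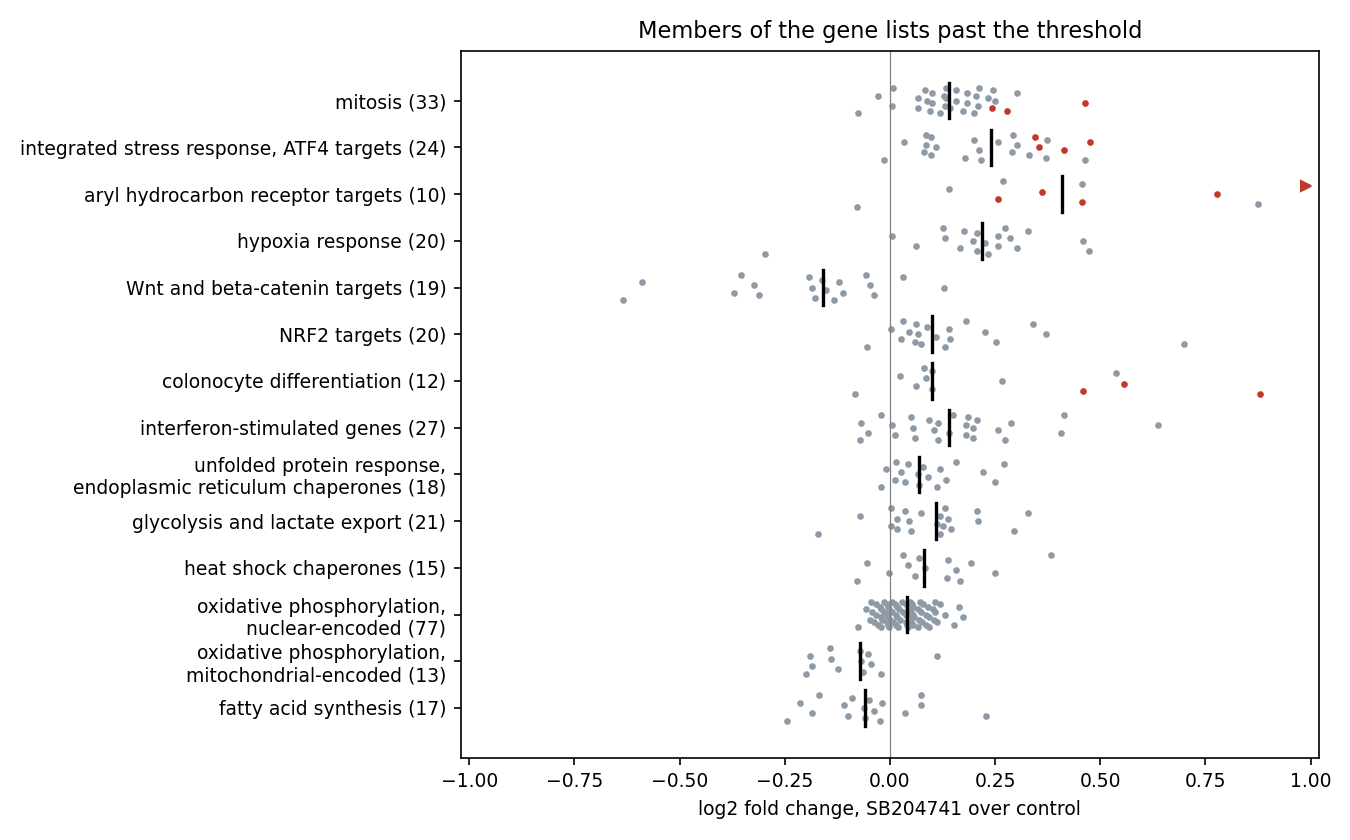
Log2 fold change (SB204741 over control, x axis) of each tested member of the 14 lists past the camera threshold, 1 point per gene, with the number of members in parentheses and the median as a bar; red points are genes past the adjusted threshold of 0.05 and the triangle is CYP1A1 at 3.22, beyond the axis. Medians lie between -0.16 and 0.41. With an estimated correlation at 4 degrees of freedom, 1 of the 14 lists, the aryl hydrocarbon receptor targets, is still called. With it at 15596 degrees of freedom, 4 of the 14 are.

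In all, 14 of 37 lists passed the camera threshold at the preset correlation, 11 higher and 3 lower. With an estimated correlation 1 passed, and 4 passed with it at the degrees of freedom of the preset test. Lists on growth and survival that did not pass were cytosolic ribosomal proteins (camera adjusted p = 0.068), mitochondrial ribosomal proteins (0.79), ribosome biogenesis and MYC (0.062), replication-dependent histones (0.061), p53 targets (0.72), apoptosis regulators (0.52), ERK pathway outputs (0.29), NF-kB and chemokine genes (0.96), epithelial-mesenchymal transition genes (0.77) and lysosome and autophagy (0.99). None of their members passed over all genes, and adjusted over the list alone only the ERK pathway outputs held any, with 1 higher and 1 lower.

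Some of these lists passed when 1 library was left out or under another setting, with camera at the preset correlation. With an estimated correlation over all 6 libraries, the camera adjusted p was 0.88 for cytosolic ribosomal proteins and 0.73 for ribosome biogenesis and MYC. In the same test it was 0.77 for replication-dependent histones and 0.88 for the ERK pathway outputs. Cytosolic ribosomal proteins passed as higher without control replicate 1 (camera adjusted p = 0.0001), control replicate 2 (0.012) or SB204741 replicate 1 (3.3e-07) and after GC correction (0.029). Ribosome biogenesis and MYC passed as lower without control replicate 1 (0.0086) or SB204741 replicate 2 (0.016), with total counts only (0.043) and after GC correction (0.049). Replication-dependent histones passed as higher without control replicate 1 (0.021), control replicate 2 (0.013) or SB204741 replicate 2 (0.0087) and with total counts only (0.027). Without control replicate 2, HIST1H1C and HIST2H2BE were called and 4 were higher adjusted over the list alone, and without SB204741 replicate 2 this was 1. The ERK pathway outputs passed as lower without control replicate 2 (0.0029). In that fit SPRY4, SPRED1, ETV4 and EPHA4 were called lower and 7 were lower over the list alone. Without control replicate 1, FOS was called and 4 were higher over the list alone. The lower member was lost without control replicate 3 or any 1 SB204741 library, and the higher one without SB204741 replicate 1 or 2. Among p53 targets, GDF15 was called higher without control replicate 1 and SESN1 lower without control replicate 2. Over the list alone there was 1 higher without control replicate 1 and 2 lower without control replicate 2 or SB204741 replicate 1. For NF-kB and chemokine genes, 1 was higher over the list alone without control replicate 2 or SB204741 replicate 3.

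Markers of other cell types stayed low or did not differ by the test. Fibroblast markers (0 of 5 tested members called, camera adjusted p = 0.79) reached 5.42 TPM in control and 6.44 TPM in SB204741 cells for COL1A1. Leukocyte markers (0 of 7 called, camera adjusted p = 0.89) included PTPRC at 1.67 and 1.84 TPM, while LYZ at 549 and 543 TPM and CD68 at 793 and 839 TPM were expressed in every library. The endothelial list had 4 tested members, too few for the list test, with 0 called and EGFL7 highest at a mean of 2.99 TPM. The list of nuclear-retained and long noncoding RNAs had 0 members in the transcript set and was not analysed here.

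Among the called genes, 3 had fewer than 3 counts in total in 1 group, and their fitted fold changes depend on the prior count and are not given. AC008758.1 (chromosome 19, 12461559 to 12551474) had 0 expected counts in control and 165.8 with SB204741, and AC048338.1 (chromosome 12, 122207779 to 122266423) had 139.9 and 0.4; both were chosen after their values were seen. Of their 31-base words, 0.3% and 2.1% occurred in no other gene, so their counts are uncertain. The remaining gene is a ribosomal protein pseudogene.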

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

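The primary-assembly, mean TPM, GC and robust named-gene fits and the list test that kept the degrees of freedom were chosen after seeing the data; the other alternatives were planned. The main test called 31 genes higher and 5 lower. Higher and lower counts were 144 and 47 by DESeq2, 7 and 0 with the offset for transcript length (1825 genes at an unadjusted p under 0.05), and 0 and 0 by limma on log2(TPM + 1) or log2(TPM + 0.1) (1640 and 1637 at an unadjusted p under 0.05). Lower genes numbered 11 with no filter and 3 with a mean of at least 50 counts. Leaving out 1 library gave 8 to 171 higher and 0 to 145 lower, with 171 and 145 without control replicate 2, 99 and 12 without control replicate 1, 11 and 1 without control replicate 3, and 9 and 1, 13 and 0, and 8 and 1 without SB204741 replicates 1, 2 and 3; fewer samples enter each fit. The cause of these differences was not tested. The other settings stayed within 1.5 times, sharing between 26 of the 36 genes (total counts only, and the replicate block) and 36 (median-ratio size factors); the robust prior shared 31 and lost CYP1A1, AREG, EREG, PLXND1 and AC048338.1. All 36 kept their direction in every setting where they were tested. Total counts only moved the median log2 fold change by -0.0211. Replicate numbers did not pair the libraries (correlations of deviations -0.00, 0.01 and -0.02); with the replicate block, 24 genes were higher, 4 lower and 14 lists called. Of 37 lists, 14 were called in the main test, 1 with an estimated correlation, 4 with it at the degrees of freedom of the preset test (aryl hydrocarbon receptor, NRF2, interferon and colonocyte lists), 2 by fry, 8 by its mixed test, 17 after GC correction and 13 to 20 without 1 library. Over the named genes, 337 of the refitted values kept their side of the threshold, 83 lost it and 13 gained it. The 83 all came from the 17 named genes called in the main test. The 337 include genes not called there, which keep their side by staying uncalled. EREG, PLXND1 and KIF2C each lost the call in 9 of 14 settings. Of values called in either fit, 0 reversed. SLC6A4 (-0.148 to 0.039) and MAOA (-0.019 to 0.035), never called, had log2 fold changes on both sides of 0. CYP1A1 ranged from 7.52-fold to 14.98-fold without 1 library. The range of adjusted p was 1.2e-08 to 0.14 for CYP1A1, 5.7e-10 to 0.089 for FABP1 and 2.7e-10 to 0.13 for CEACAM5. HTR2B had 4.3 counts on the primary assembly too. Depth limits statements on genes near 3 counts, HTR2B included.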

Other observations

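The called genes in this paragraph lie outside the rule for named genes and were chosen after their values were seen. UGDH, which makes UDP-glucuronic acid, rose 1.21-fold (log2 fold change 0.28 ± 0.05, SE; adjusted p = 0.036), and the bilirubin glucuronosyltransferase UGT1A1 rose 1.32-fold (0.40 ± 0.06; adjusted p = 0.011), with 47.8% of its 31-base words in no other gene; it shares sequence with UGT1A6 of the same locus, so the 2 calls are not separate evidence. The nuclear receptor PPARG rose 1.26-fold, from a mean of 33.8 to 43.3 TPM (0.33 ± 0.06; adjusted p = 0.0321), and the galectin LGALS3 rose 1.27-fold, from 460 to 572 TPM (0.34 ± 0.05; adjusted p = 0.0274). ATF3, a stress-induced transcription factor, rose 1.33-fold (0.41 ± 0.07; adjusted p = 0.0386). Each of these 5 calls ended in some fits that left out 1 library: without control replicate 3, SB204741 replicate 2 or SB204741 replicate 3 for all 5, and without SB204741 replicate 1 for all but UGT1A1, with highest adjusted p of 0.22, 0.11, 0.2, 0.16 and 0.25 in the order named.

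Of the tests that follow, those of gene counts over other splits and of single libraries were chosen after the results were seen. So was that of shared reads for the aryl hydrocarbon receptor list. Over the 10 splits of the 6 libraries into 3 and 3, the real split called 36 genes and the highest of the others 1; as many genes as in the real split came from 1 of the 10. For gene lists the real split called 14 and the others between 7 and 17, with as many or more in 3 of the 10. Splits this few cannot give a share under 0.05.

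The rise of the aryl hydrocarbon receptor list as a whole did not rest on 1 library, since the highest camera adjusted p over the fits leaving out each library was 6.5e-11, though the calls of its members fell from 5 to 2 without SB204741 replicate 3. Reads shared with other genes are argued against as its whole cause, because the 9 members with at least 90% of their 31-base words in no other gene, 8 of them above 0, still passed without UGT1A6 (adjusted p of 4.8e-11), and so is GC content, with an adjusted p of 1.3e-13 after the correction. A hypothesis is that the receptor was more active in the treated cultures. A second list of 9 targets, written before its values were seen, was higher by camera with a preset correlation (p = 0.025). Of its 7 tested members 6 lay above 0 and 0 were called, and the camera p was 0.082 with an estimated correlation. The p of 0.025 is unadjusted and weak evidence, since camera at the preset correlation called 7 to 17 of 37 lists in the other splits. The first list passed in 5 of the 9 other splits, with a lowest adjusted p of 0.011 against 2.6e-13, and in the same direction in all 5, where each still sets 2 treated libraries against 1. Whether SB204741, its vehicle or another difference between cultures could account for the rise is open and was not tested.

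For the small shifts of the mitosis, stress response, hypoxia and Wnt lists, GC content of the genes is argued against as the whole cause, because 4 of the 4 lists still passed after the correction. Variation between cultures of one group that moves the same genes stays open: in 3 of the 9 other splits at least 3 of the 4 lists passed the camera threshold. That test cannot decide, since every other split still sets 2 treated libraries against 1. In these 3 splits the lists moved in the same direction as in the real one. The hypoxia list alone passed in 6 of the 9, and in 1 of these in the opposite direction (camera adjusted p = 0.0031). Its lowest camera adjusted p in another split was 1.3e-16, in the same direction, against 4.8e-11 in the real split. With each list at its estimated correlation within groups and the degrees of freedom of the preset test, in a test also chosen after the results were seen, the adjusted p was 0.062, 0.092, 0.17 and 0.13 in that order. Such variation and an effect of SB204741 cannot be told apart with 3 libraries a group.

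For AC008758.1 and AC048338.1, listed at or near 0 in one group, reads moved between genes that share sequence are a candidate explanation: at most 2.1% of the 31-base words of either gene occurred in no other gene. The closest genes were ZNF709, with 96.8% of the words of AC008758.1, and VPS33A, with 57% of those of AC048338.1. No biological explanation was tested for these genes.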
